A study of Mus musculus with 6 samples.

How the data were processed

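Total RNA of the whole brain of mouse embryos at embryonic day 14.5 was measured on 6 Agilent 1-colour arrays, 3 from wild-type embryos and 3 from Ts1Cje embryos. Groups and replicate numbers came from the sample titles. Per the labels' protocols, Cy3-labelled cRNA was made from 0.1 ug of RNA per sample with a low-input amplification kit. The series text speaks of 3 pairs of Ts1Cje embryos and wild-type littermates, and does not say whether a sample is 1 embryo or a pool. The p-values therefore measure the spread between these samples.

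Per the file headers, the deposited scanner files hold spot intensities read with Agilent Feature Extraction version 10.10.1.1 under protocol GE1_1010_Sep10, with array annotation on genome build mm9. Each file holds 62976 spots, of which 3671 are controls. The processed intensity is background-corrected and not scaled between arrays. The deposited flags mark spots that are uneven, outlying, saturated or well above background. The authors' deposited table holds normalized intensities for 30066 non-control probes, a p-value, a corrected p-value and a signed fold change, which was read as a score with the sign of the direction and no values between -1 and 1. How that table was normalized is not given in the sources used here. No spot was saturated, and 138 to 152 non-control spots per array were flagged as uneven or outlying and left out. Averaging the spots of a probe gave 55681 non-control probes, of which 37 had every spot flagged on at least 1 array and were left out.

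Probes were named through a reference gene table of assembly GRCm38.p6. A gene name came from the probe's accession for 26576 probes and from the Entrez ID of the deposited table for 2168, and 26937 probes stayed unnamed. Where a probe had both names, they gave the same gene for 99.9% of 18736 probes. The array held 21790 named genes. The assembly differs from the build of the array, so it served for names, chromosomes and the order of neighbouring genes, and no coordinates are given.

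From the intensities, log2 values minus the 75th percentile of each array over its non-control probes were computed. Probes well above background on all arrays of at least 1 group were kept, and each gene was represented by the probe with the highest mean over the 6 arrays. This left 23012 genes or unnamed transcripts, 16304 of them named. Ts1Cje was compared with wild-type by lmFit and eBayes of limma version 3.58.1 in R version 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 fold changes are standard errors (SE) of this fit, and intervals are 95% intervals. Files were read with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. Where a probe was not well above background on any array of a group, a fold is given as at least the ratio of the bright group's mean to the dim group's mean, with each dim array set to the higher of its own value and the lowest signal among its probes well above background.

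For 41 gene lists written before the data were examined, the median log2 fold change of the tested members is given with the result of limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Lists needed at least 5 tested members. Of 792 list entries, 784 matched a gene on the array. The tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took the 8 highest and 4 lowest members of the triplicated list, 10 fixed genes of or near that segment, every tested member of the deleted list, up to 10 genes per direction outside both lists, up to 4 members of each list with the greatest absolute change, and 5 sex-linked genes. Outside the lists, the genes past the threshold with no overlap between groups came ahead, filled up by the smallest unadjusted p among non-overlapping genes with at least a 1.5-fold change.

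The 6 arrays lay on 3 slides scanned on 3 days, and each slide and day held the wild-type and the Ts1Cje array of 1 replicate number. The deviations of the arrays from their group means correlated across genes at 0.675, 0.766 and 0.668 within the numbers 1, 2 and 3, against at most -0.17 between different numbers. Genes are not independent replicates in these correlations. The numbers therefore pair the samples, through the slide and scan day or through the litter, which cannot be separated here. The planned fit has no block, so its standard errors include the spread between slides. Values with the slide as a random block (duplicateCorrelation, consensus correlation 0.822) or as a fixed block are given beside results that they change. Differences within slides are also given. The random block applies 1 correlation to all genes, so its p-values can be too small for genes whose differences vary widely between slides.

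The steps were tested on simulated data with 200 changed genes among 23012 and a within-slide correlation of 0.8. In a single simulated draw, genes changed 1.5-fold were recovered in 0% of cases without a block, in 37.3% with a fixed block and in 70.1% with a random block. For 2-fold changes these shares were 32.8%, 73.1% and 83.6%, and for 4-fold changes 74.2%, 90.9% and 98.5%. Of the unchanged genes, 0, 4 and 5 were called, and the camera p was under 0.05 for 1 of 100 unchanged sets of 20 genes. The simulated genes were drawn independently of each other. The simulated sets therefore say nothing about camera for lists whose members correlate.

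Alternatives covered quantile and median scaling, another background correction, other filters on dim probes, other rules for genes with several probes, moderation with a trend, blocks, each array left out in turn, removal of genes on chromosomes X and Y, other set tests and other thresholds. The mean spot signal was not in the scanner files used here, so normexp with an offset of 50 used the median spot signal and the median local background in its place. The authors' normalized intensities were tested in the same limma fit as an alternative chosen after seeing the data. The number of arrays limits the precision.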

Results

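The series measured gene expression in the whole brain of Ts1Cje mouse embryos and wild-type littermates at E14.5, with 3 arrays per group. Ts1Cje mice model Down syndrome: they carry an extra copy of the distal part of chromosome 16, which matches part of human chromosome 21, and lack 1 copy of the telomeric end of chromosome 12. The extra copy of Sod1, at the start of the segment, is disrupted. The comparison asks how the added and missing copies change transcript levels in the embryonic brain, and which genes elsewhere differ. Between 31855 and 37110 probes per array, 57.2% to 66.7%, were well above background. The 75th percentile of the processed signal lay between 781 and 1344, highest on the slide of replicate 3. Correlations between arrays over the tested genes were 0.985 to 0.996, and arrays of the same slide lay closer together (lowest correlation 0.995) than arrays of different slides (highest 0.990).

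Genes of the triplicated segment were higher in Ts1Cje as a group. The 60 tested members of the list had a median log2 fold change of 0.52, a 1.44-fold level, and 59 of them were above 0. The median of the differences within slides was 0.54, 0.54 and 0.51 on slides 1, 2 and 3, and 54 members were higher on every slide. The list passed camera at an adjusted p of 2.2e-97, and at an adjusted p of 4.8e-04 with an estimated correlation. An added copy transcribed like the other copies would give a level of 1.5-fold (log2 0.58). With the slide as a random block, the 95% intervals of 51 members held that value, 7 lay below it and 2 above it. The median stayed between 0.49 and 0.54 without any 1 array.

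Without a block, 0 of the 60 members passed limma's adjusted threshold over all genes, while 47 had an unadjusted p under 0.05 and 43 passed when adjusted over the list alone. With the slide as a random block 33 rose over all genes and 54 when adjusted over the list alone, and with a fixed block 0 passed over all genes. The 33 became 1, 1 and 26 without wild-type replicate 1, 2 and 3, and 0, 3 and 7 without Ts1Cje replicate 1, 2 and 3. The genes that rose in the random-block fit include Dyrk1a, a kinase studied for its role in brain size, at a log2 fold change of 0.55 ± 0.14 (SE, n = 3 per group), Rcan1, an inhibitor of calcineurin, at 0.50 ± 0.14, the transcription factor Ets2 at 0.52 ± 0.13, and Sod1, the copper-zinc superoxide dismutase, at 0.74 ± 0.13. Their adjusted p-values with the random block were 0.025, 0.028, 0.021 and 0.016. The errors given here are those of the fit without a block. With the random block the SE of Dyrk1a was 0.06. Sod1 was counted outside the list because its extra copy is disrupted. Whether its probe also takes up transcript of the disrupted copy was not tested. App, proximal to the segment, had a log2 fold change of 0.00 ± 0.11.

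The highest members were Igsf5 at 1.11 ± 0.29, Bace2, a protease related to the beta-secretase, at 0.93 ± 0.12, Tmem50b at 0.78 ± 0.14, the carbonyl reductase Cbr3 at 0.78 ± 0.12, the haematopoietic transcription factor Runx1 at 0.74 ± 0.16, Dop1b at 0.66 ± 0.12 (0.98 by its other probe), the calmodulin-binding protein gene Pcp4 at 0.64 ± 0.14 and Donson at 0.64 ± 0.13. Of these 8, Bace2, Tmem50b, Cbr3, Dop1b and Donson passed with the random block. The Igsf5 probe was well above background on 1 of 3 wild-type arrays and the Prdm15 probe on 2 of 3 Ts1Cje arrays. The lowest were Sim2 at -0.10 ± 0.25 (0.08 by its other probe), Olig2 at 0.01 ± 0.20, Itsn1 at 0.04 ± 0.16 and Prdm15 at 0.12 ± 0.69, and none of these 4 passed in any of the 3 fits. Olig2 and Olig1, transcription factors of the oligodendrocyte lineage, lie next to each other in the segment, and Olig1 was at 0.36 ± 0.18 with a random-block adjusted p of 0.49. The Itsn1 value depends on the probe: 6 other probes of the gene gave 0.51 to 0.64. Dscam, a cell adhesion gene, was at 0.53 ± 0.21 and Erg at 0.36 ± 0.39, and neither passed in the random-block fit.

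In gene order, the shift began at Sod1. The 453 tested named genes of chromosome 16 proximal to Sod1 had a median log2 fold change of -0.01, and for the 20 nearest to it the median was 0.00. The nearest neighbours on that side, Gm2805 and Tiam1, were at 0.01 and 0.07. The 65 genes distal to Sod1 had a median of 0.52. The list of 22 genes proximal to Sod1 had a median of 0.00 (camera adjusted p = 0.95), and the 29 human chromosome 21 orthologues on mouse chromosomes 10 and 17 had a median of -0.02 (camera adjusted p = 0.95). Across whole chromosomes, medians of named genes lay between -0.02 on chromosome 12 and 0.01 on chromosome 16.

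**Figure D1:**
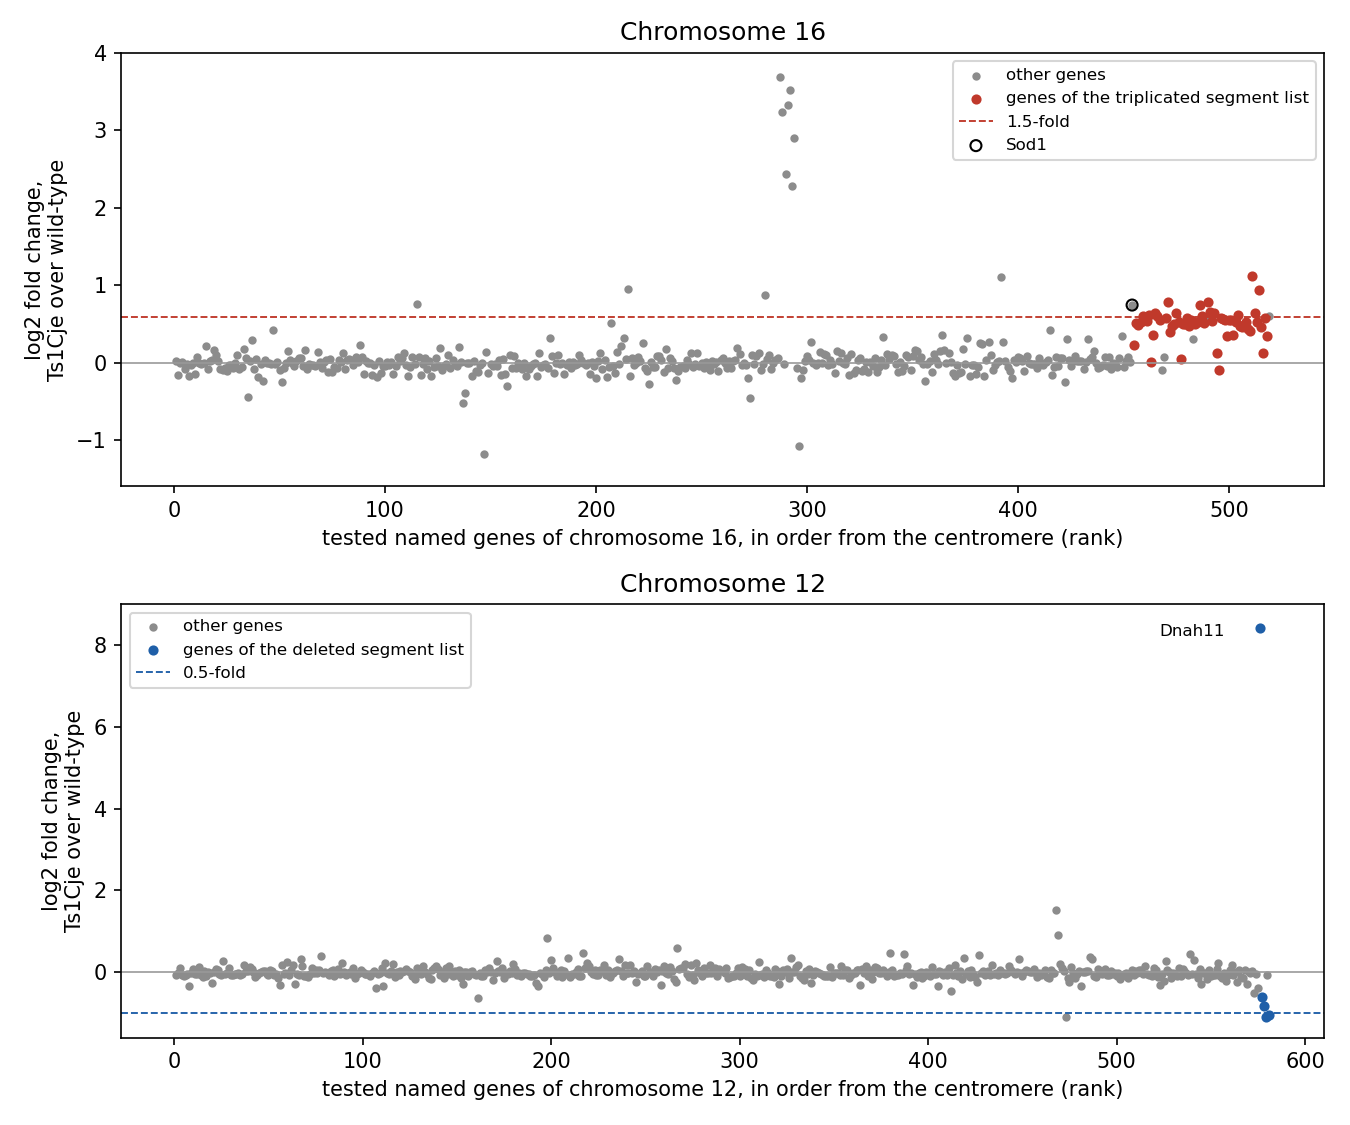
Log2 fold change of Ts1Cje over wild-type (y axis) for each tested named gene of chromosomes 16 and 12, ranked along the chromosome from the centromere (x axis), with list members in colour and the 1.5-fold and 0.5-fold levels as dashed lines. The 65 genes distal to Sod1 have a median of 0.52, the end of chromosome 12 holds lower genes, and Dnah11 stands at 8.42.

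On the deleted segment of chromosome 12, 4 of the 5 tested genes were lower in Ts1Cje and 1 was far higher. The zinc-finger transcription factor genes Sp8 and Sp4 had log2 fold changes of -0.83 ± 0.15 and -0.61 ± 0.32, the integrin subunit gene Itgb8 -1.10 ± 0.26, and Tmem196 -1.05 ± 0.34, on every slide below 0. Their median was -0.94, a level lower by 1.92-fold, with within-slide medians of -0.65, -1.10 and -0.93. Sp8 and Itgb8 fell with the slide as a random block, with adjusted p-values of 0.017 and 0.016, and Sp4 and Tmem196 did not pass over all genes. Tmem196 was well above background on 2 of 3 Ts1Cje arrays. Dnah11, which encodes an axonemal dynein heavy chain of motile cilia, was higher by a log2 fold change of 8.42 ± 0.16, a 342-fold level, at 8.31, 8.47 and 8.48 on the 3 slides. It passed limma's test without a block (adjusted p = 2.3e-05), with a fixed block and with a random block, and its single probe on the array was well above background on all 6 arrays. One other probe of Sp8 gave -0.22.

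The whole list of 5 had a median of -0.83 and a mean of 0.97, because of Dnah11. Camera ranked the list lower at an adjusted p of 0.026, and the call was lost with an estimated correlation (adjusted p = 0.32), while fry, which is moved by Dnah11, called the list higher (adjusted p = 1.3e-04). The call of camera was also lost with normexp (median -0.60, adjusted p = 0.087), with no filter on dim probes (median -0.61, adjusted p = 0.32) and with the mean of a gene's probes (median -0.61, adjusted p = 0.063). It was lost without wild-type replicate 2 (adjusted p = 0.15), Ts1Cje replicate 2 (0.14), wild-type replicate 3 (0.21) or Ts1Cje replicate 3 (0.088). Abcb5 and Macc1 were not well above background on any array. Next to the segment, Cdca7l was at -0.39 and Rapgef5 at -0.05, and the list of 7 genes proximal to the deletion had a median of -0.05 (camera adjusted p = 0.13).

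Over the whole array, 2 genes passed limma's threshold without a block, Dnah11 and Csta2, both higher, and 377 had an unadjusted p under 0.05 (295 higher, 82 lower). With the slide as a fixed block 1 gene passed, Dnah11. With the slide as a random block 122 passed, 108 higher and 14 lower: 33 on the triplicated list, 3 on the deleted list and 86 on neither list, of which 59 were named (53 higher, 6 lower). Of these 59, Sod1, Gm5678 and A630089N07Rik lie at the start of the triplicated segment or distal to it. That count rests on all arrays: it was 10 without wild-type replicate 1, 4 without Ts1Cje replicate 1, 24 without wild-type replicate 2, 29 without Ts1Cje replicate 2, 43 without Ts1Cje replicate 3 and 163 without wild-type replicate 3. Of the 122 genes, 8, 3, 22, 24, 30 and 77 were among these, in the same order. The groups did not overlap for 4.27% of the tested genes. Chance gives 10% for 3 against 3 arrays that share nothing, which is no reference for arrays that share slides.

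Outside both segments, transcripts of several granulocyte proteins were higher in Ts1Cje. S100a8 and S100a9, which encode the subunits of calprotectin, had log2 fold changes of 3.36 ± 0.61 and 3.29 ± 0.51. The genes of lactoferrin (Ltf), myeloperoxidase (Mpo) and the cathelicidin peptide (Camp) were at 2.55 ± 0.40, 1.99 ± 0.42 and 1.59 ± 0.25. These 5 rose in the random-block fit, with adjusted p-values from 0.016 to 0.024, and their differences were above 1 on every slide. The random block applies 1 correlation to all genes, and its SE was 0.37 for S100a8 and 0.36 for S100a9. Between slides their differences ran from 2.26 to 4.38 and from 2.19 to 4.34, so these p-values may understate the spread. Without wild-type replicate 1, 2 or 3, 0, 4 and 6 members of the granulocyte list passed in the random-block fit. Without Ts1Cje replicate 1, 2 or 3 the numbers were 0, 4 and 1. The Ltf probe was well above background on 1 of 3 wild-type arrays, and the other probe of Camp gave 1.16. Of the 14 tested members of the granulocyte list, 8 were higher at an unadjusted p under 0.05, 7 when adjusted over the list alone, and 0 over all genes without a block. Of the other members, named after their values were seen, Csf3r at 0.11, Chil3 at 0.13, Elane at 0.37, Mmp9 at -0.26 and Prtn3 at -0.25 did not move with them.

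The granulocyte list had a median of 1.24 and passed camera (adjusted p = 1.1e-16), a call that was lost with an estimated correlation (adjusted p = 0.13). Within slides its median was 1.55, 0.68 and 0.84. The median was 0.41 with normexp, 0.44 among probes well above background on all 6 arrays, 0.43 with the authors' normalized intensities, 0.75 without a filter on dim probes and 0.66 without wild-type replicate 3, and camera called the list higher in each. On the same slides the erythroid list was at -0.45, 0.03 and 0.10 (13 tested, median -0.01, camera adjusted p = 0.59) and the microglia and macrophage list at 0.24, 0.06 and -0.34 (19 tested, median 0.00, camera adjusted p = 0.68). Within the latter, Lyve1 was at 0.62 ± 0.19, F13a1 at 0.51 ± 0.14 and Mrc1 at 0.29 ± 0.19, and none of these 3 passed over all genes in either fit.

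Several genes of a stefin A cluster, which encode cysteine protease inhibitors, were also higher. They stood on no gene list, so no set test covered the cluster. Csta2 was at least 3.91-fold higher (log2 2.43 ± 0.17 as measured, limma adjusted p = 0.045), and its probe was not well above background on any wild-type array. Stfa3 was at 2.90 ± 0.27 and Stfa2 at 2.29 ± 0.32, with random-block adjusted p-values of 0.0051 and 0.018. These genes lie on chromosome 16 far proximal to Sod1, with 160 or more tested named genes between, and their sequences are alike, so a probe of 1 member can take up transcripts of another. The call of Csta2 was lost with the quantile scaling, with normexp, with trend moderation, with no filter and with the fixed block, and its log2 fold change was 0.89 with normexp. It was also lost without wild-type replicate 1 (adjusted p = 0.57), 2 (0.057) or 3 (0.10) and without Ts1Cje replicate 1 (0.51), 2 (0.43) or 3 (0.52).

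Other higher genes of the fixed rule, none of which passed without a block, were Ly6c1, a surface marker of monocytes and endothelium, at 1.12 ± 0.15 (0.74 by its other probe), Madcam1, an endothelial addressin, at 0.83 ± 0.12, the protease inhibitor gene Slpi at 1.28 ± 0.19 and 9330102E08Rik at 0.89 ± 0.12. All 4 rose with the slide as a random block, with adjusted p-values of 0.010, 0.0067, 0.040 and 0.016. Among lower genes, Tbx1, a T-box transcription factor gene on chromosome 16 proximal to the segment, was at -1.18 ± 0.14, the calcium-binding protein gene Scgn at -0.74 ± 0.16 and the amino acid transporter gene Slc3a1 at -1.08 ± 0.27. These 3 fell in the random-block fit, with adjusted p-values of 0.0041, 0.018 and 0.037. The Slpi probe was well above background on 1 of 3 wild-type arrays, Scgn on 2 of 3 Ts1Cje arrays and Slc3a1 on 1 of 3. Fgf3 at -0.80, 1110032A03Rik at -1.04, Ccl28 at -0.62, 4930579K19Rik at -0.59, Ifnlr1 at -0.61 and Smok3b at -1.02 passed in no fit. Except for Smok3b, their probes were well above background on 1 or 2 of 3 Ts1Cje arrays. The Smok3b value came mostly from slide 1, at 0.45 in wild-type and -2.27 in Ts1Cje. Its levels were -1.05 and -1.37 on slide 2 and -1.37 and -1.40 on slide 3.

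**Figure D2:**
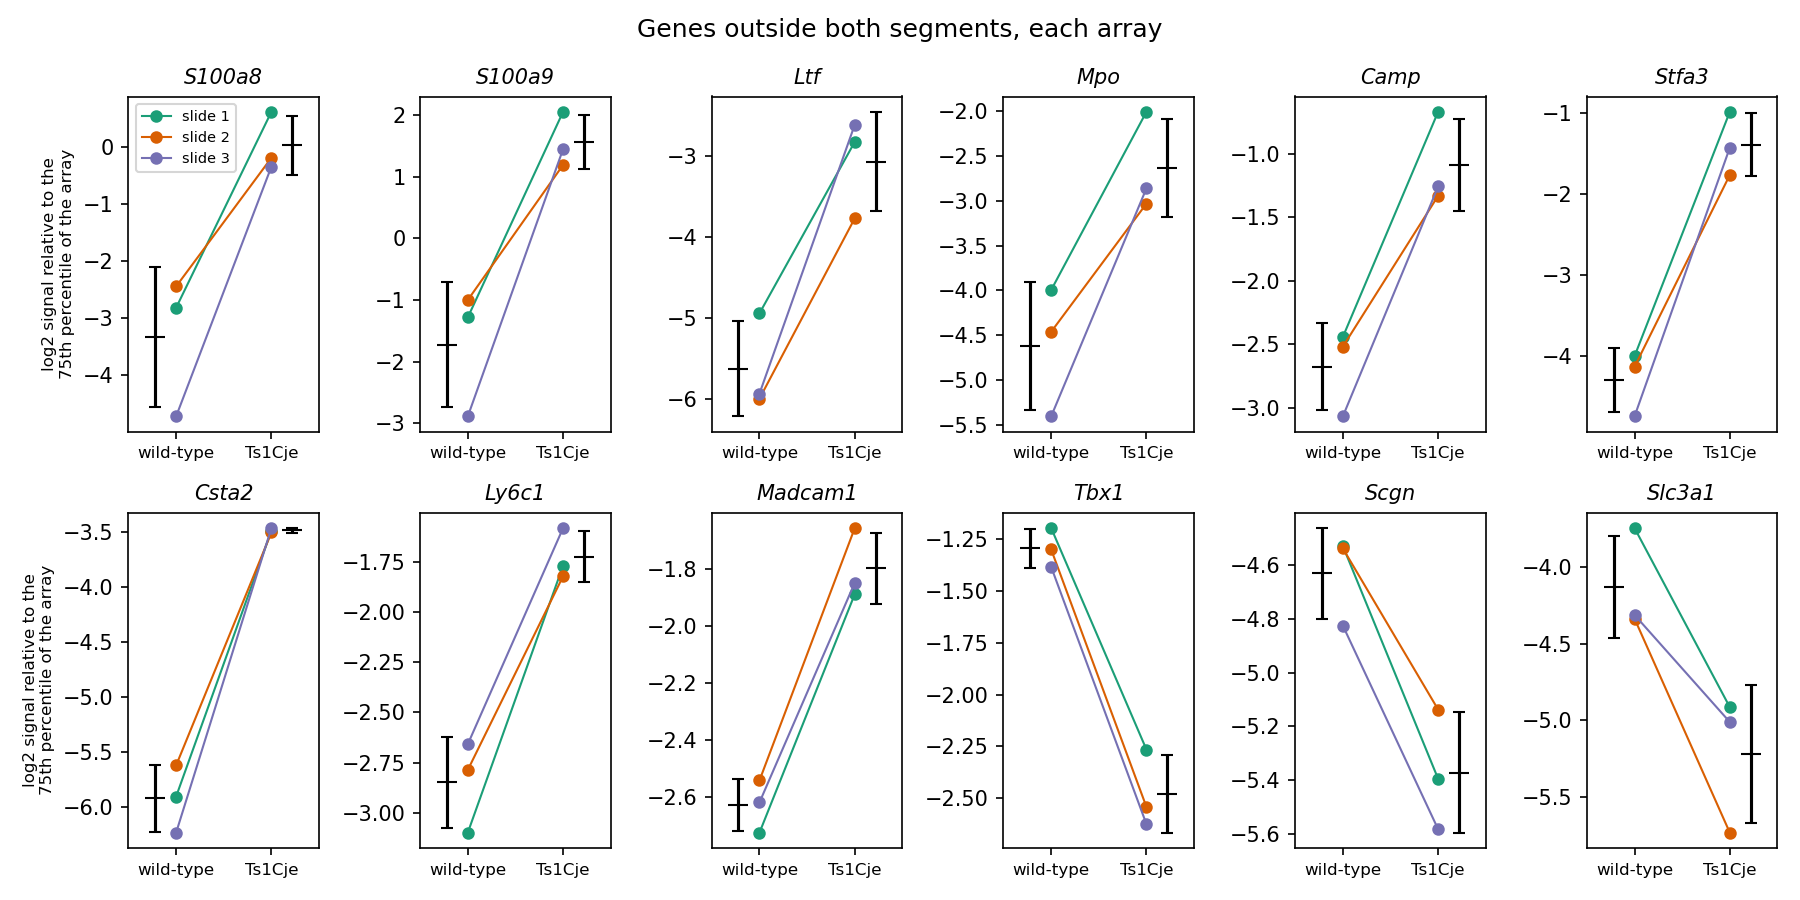
Log2 signal relative to the 75th percentile of the array (y axis, a scale of its own in each panel) for 12 genes outside both segments, with 1 point per array, lines joining the arrays of a slide, and black bars for the mean ± SD of 3 arrays per group. On each slide the 9 higher genes lie above wild-type and Tbx1, Scgn and Slc3a1 below it.

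Of the 41 gene lists, 15 passed camera, among them the triplicated, deleted and granulocyte lists. With an estimated correlation the triplicated list alone passed. Interferon response genes had a median of 0.50 (20 tested, 17 above 0, camera adjusted p = 3.2e-07; adjusted p = 0.43 with an estimated correlation), and the slides differed: their within-slide medians were 0.91, 0.58 and -0.12. Ifi27, an interferon-induced gene, was at 0.91 ± 0.16 and rose in the random-block fit (adjusted p = 0.016). Oas1a was at 0.98 ± 0.51 and Xaf1 at 0.78 ± 0.31, and neither passed in any fit. The median was 0.20 without wild-type replicate 1, 0.28 without wild-type replicate 2 and 0.82 without wild-type replicate 3. Without both arrays of slide 1 the list had a median of 0.16 and did not pass (camera adjusted p = 0.19).

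Lists of markers of the meninges and vessels had medians above 0 and passed camera at the preset correlation alone, not with an estimated correlation or by fry. The meninges and mesenchyme list had a median of 0.19 (16 of 16 tested members above 0, camera adjusted p = 3.2e-07; adjusted p = 0.13 with an estimated correlation), at 0.25, 0.06 and 0.26 within slides. Its members Aldh1a2, a retinoic acid synthesis gene, the collagen gene Col1a1, the transporter gene Slc6a13 and Ogn were at 0.38 ± 0.12, 0.38 ± 0.20, 0.35 ± 0.14 and 0.34 ± 0.15. The pericyte and smooth muscle list had a median of 0.15 (11 of 12 above 0, camera adjusted p = 0.0011; adjusted p = 0.18 with an estimated correlation), with Acta2, smooth muscle actin, at 0.49 ± 0.24 and Tagln at 0.61 ± 0.99, and did not pass without Ts1Cje replicate 3 (adjusted p = 0.10). Tagln differed widely between replicates 1, 2 and 3, at 0.15, 2.98 and 0.54 in wild-type and 0.42, 3.46 and 1.62 in Ts1Cje. The endothelial list had a median of 0.08 (camera adjusted p = 0.0068; adjusted p = 0.50 with an estimated correlation), with Vwf at 0.69 ± 0.32 and Cdh5 at 0.27 ± 0.12. Its adjusted p was 0.077 without Ts1Cje replicate 1, 0.19 without wild-type replicate 2 (median 0.05) and 0.72 without Ts1Cje replicate 3 (median 0.04), and its median was 0.16 without Ts1Cje replicate 2. None of the 8 members named here passed over all genes in any fit.

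Lists of neurons and progenitors had medians within 0.1 of 0 for most types. The GABAergic and ganglionic eminence list was lower, with a median of -0.10 (17 of 20 members below 0, camera adjusted p = 0.0016; adjusted p = 0.43 with an estimated correlation). Gsx1, Nkx2-1, Dlx5 and Dlx1, transcription factors of the ganglionic eminences or their neurons, were at -0.42 ± 0.20, -0.34 ± 0.26, -0.25 ± 0.26 and -0.23 ± 0.14. The within-slide medians were -0.02, -0.35 and -0.04, and the list had a median of -0.03 without wild-type replicate 2 (adjusted p = 0.53) and of -0.17 without wild-type replicate 3. The median was -0.03 for cortical projection neurons, -0.02 for postmitotic neurons, -0.04 for radial glia and neural stem cells, -0.03 for intermediate progenitors and -0.08 for monoaminergic and cholinergic neurons, with camera adjusted p-values of 0.13, 0.57, 0.59, 0.16 and 0.35. None of the members of these 6 lists passed over all genes in any fit. The midbrain and hindbrain list had a median of -0.27 (8 tested, camera adjusted p = 0.040; adjusted p = 0.54 with an estimated correlation), with Pax7 at -0.54 ± 0.95 (well above background on 2 of 3 Ts1Cje arrays) and Otx2 at -0.34 ± 0.21. Its within-slide medians were -0.66, -0.53 and 0.39. It did not pass with the slide as a fixed or random block (adjusted p = 0.14 and 0.092), nor without wild-type replicate 1 (median 0.18), Ts1Cje replicate 1 (-0.37), wild-type replicate 2 (-0.18) or Ts1Cje replicate 2 (-0.09). Without wild-type replicate 3 its median was -0.51. It also lost the call with median scaling (adjusted p = 0.053), with no filter on dim probes (0.15) and with the authors' normalized intensities (0.056).

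Of the remaining lists past camera, mast cell and megakaryocyte markers had a median of 0.14 (adjusted p = 0.0062; 0.43 as the adjusted p with an estimated correlation), and the platelet chemokine gene Ppbp, at 0.77 ± 0.15, rose in the random-block fit. Hypoxia and glycolysis genes had a median of 0.17 (camera adjusted p = 0.0062; adjusted p = 0.43 with an estimated correlation), with Adm at 0.36 and Pfkp at 0.31 (0.06 by its other probe). Astrocyte markers had a median of 0.12 (camera adjusted p = 0.013, and 0.27 with an estimated correlation). Among them were S100b at 0.76 ± 0.52 (well above background on 2 of 3 wild-type arrays) and Agt at -0.35 ± 0.39. The S100b value came mostly from wild-type replicate 1, at -5.93 against -3.94 and -4.42 in replicates 2 and 3. In Ts1Cje S100b was at -3.71, -3.78 and -4.53. The within-slide medians of the astrocyte list, 0.14, 0.21 and -0.10, differed in sign. Mitosis genes had a median of -0.08 (camera adjusted p = 0.0097; adjusted p = 0.63 with an estimated correlation), with Kif11 at -0.18 and Plk1 at -0.12, and a fixed-block adjusted p of 0.077. Their within-slide medians were -0.01, -0.30 and 0.09, so the lower value came from slide 2. Monocyte and dendritic cell markers had a median of 0.06 (camera adjusted p = 0.012; adjusted p = 0.27 with an estimated correlation), and skin, muscle and cartilage genes a median of 0.12 (camera adjusted p = 0.043; adjusted p = 0.43 with an estimated correlation). With the slide as a fixed and as a random block the last 2 lists did not pass, at adjusted p-values of 0.14 and 0.072 for the former and 0.19 and 0.12 for the latter.

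Each of these 6 lists lost its call without some single arrays. The mast cell list had a median of 0.06 without Ts1Cje replicate 1 (adjusted p = 0.18) and of 0.05 without wild-type replicate 3 (0.28), and the hypoxia list of 0.13 without wild-type replicate 2 (0.17) and of 0.06 without Ts1Cje replicate 3 (0.70). The astrocyte list did not pass without replicate 1 or 2 of either group (adjusted p from 0.055 to 0.15). The mitosis list did not pass without wild-type replicate 1 (0.072) or 2 (0.18), and had a median of 0.03 without Ts1Cje replicate 2 (0.80). The monocyte list did not pass without Ts1Cje replicate 1 (0.11), wild-type replicate 2 (0.15) or Ts1Cje replicate 3 (0.11), and the skin, muscle and cartilage list passed without wild-type replicate 1 alone (0.019). The median of the mast cell list was 0.23 without wild-type replicate 1, of the hypoxia list 0.28 without Ts1Cje replicate 2, of the astrocyte list 0.04 and 0.19 without wild-type replicates 2 and 3, and of the mitosis list -0.16 without Ts1Cje replicate 3. Calls were also lost for the mast cell list with normexp (adjusted p = 0.057) and with no filter on dim probes (0.12), and for the astrocyte list with the mean of a gene's probes (0.061). The monocyte list lost it with the quantile scaling (0.073), no filter (0.058) and the authors' normalized intensities (0.056), and the skin list with these 3 (0.12, 0.10 and 0.096) and normexp (0.099).

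**Figure D3:**
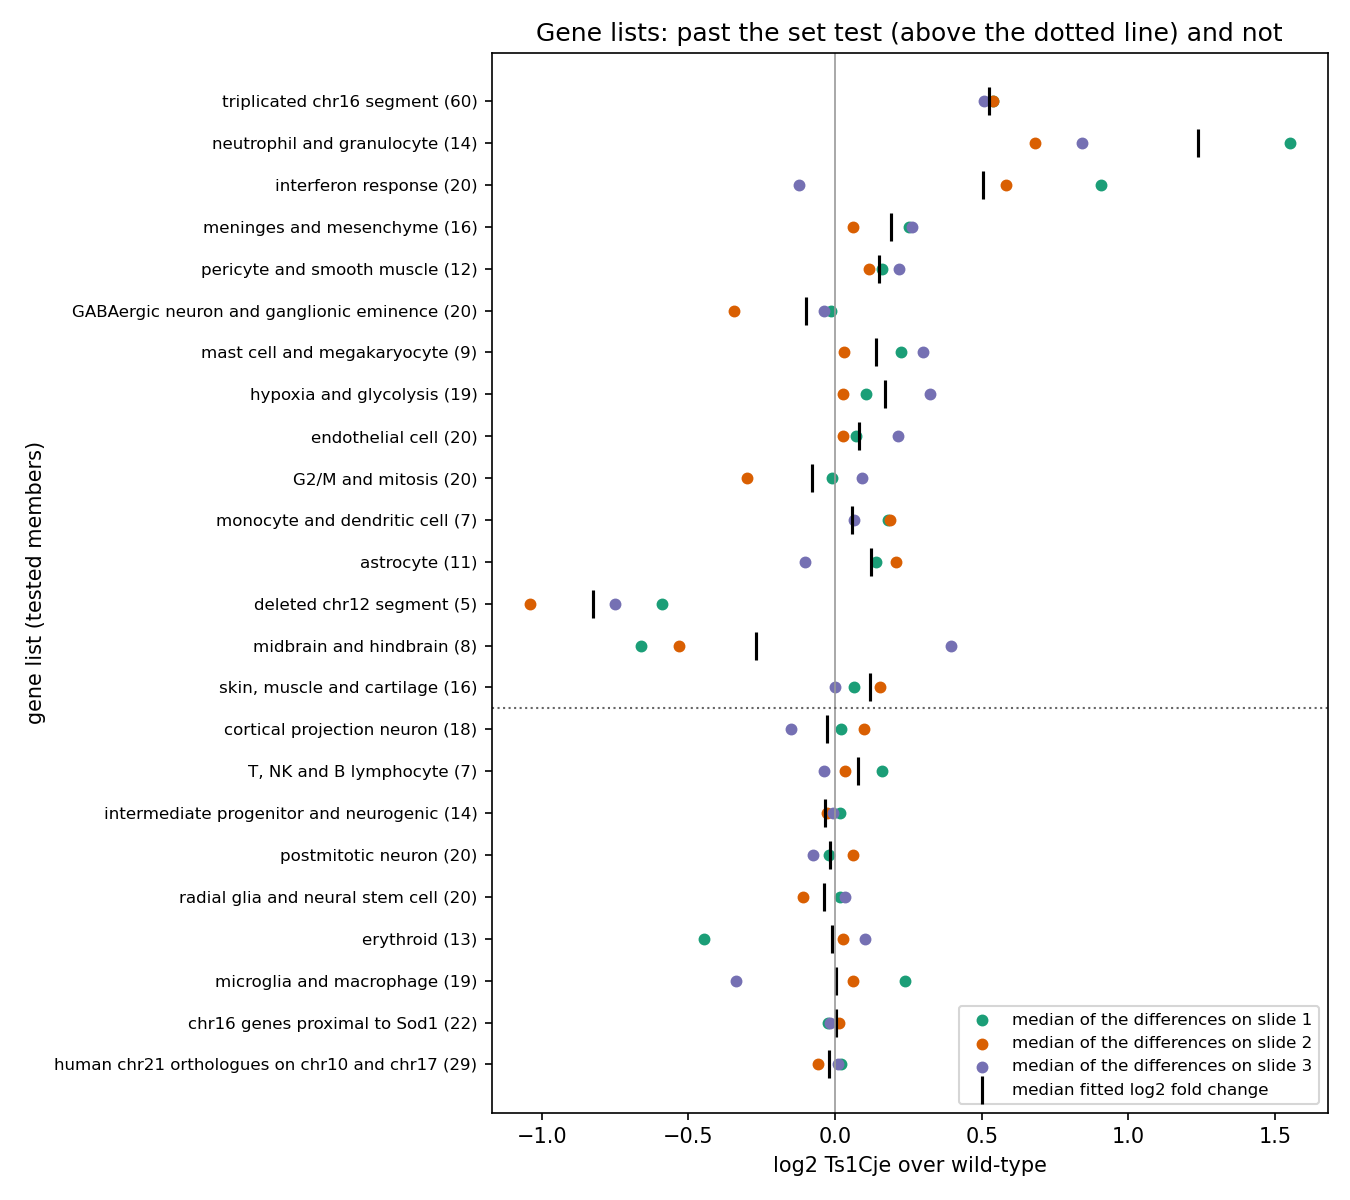
Median log2 ratio of Ts1Cje over wild-type (x axis) for gene lists (y axis, tested members in parentheses), with a coloured point for the median of the differences within each slide and a black bar for the median fitted log2 fold change. The 15 lists above the dotted line passed camera; the triplicated list has within-slide medians of 0.51 to 0.54, while those of the interferon, midbrain, astrocyte and mitosis lists lie on both sides of 0.

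The lists that did not pass camera, besides those already given, had medians between -0.13 and 0.10. These were hypothalamus and pituitary (-0.13), calcineurin, NFAT and Dyrk1a partners (-0.04), Wnt signalling (-0.05), lymphocytes (0.08), cholesterol synthesis (-0.02), eye, lens and retina (0.05), chemokines and inflammatory cytokines (0.10), DNA replication (-0.03), oxidative phosphorylation (-0.01), choroid plexus (0.01), oligodendrocyte lineage (0.04), p53 and apoptosis (-0.01), antioxidant genes (0.01), unfolded protein and heat shock response (0.00), hedgehog and Notch targets (0.02) and sex-linked genes (-0.03). Their camera adjusted p-values ran from 0.071 to 0.95. The hypothalamus and pituitary list passed under 6 of 19 alternatives, with medians from -0.29 without Ts1Cje replicate 2 (adjusted p = 9.6e-04) to 0.00 without Ts1Cje replicate 3 (0.20), and no other of these lists passed under more than 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background on all 6 arrays, with log2 fold changes of 0.05 ± 0.12, -0.08 ± 0.22, -0.27 ± 0.17 and 0.40 ± 0.27. One other probe of Uty gave 0.04. The X-linked gene Xist was well above background on at most 1 array per probe.

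In the authors' deposited table the fold change is headed as Ts1Cje over wild-type, but its sign is the opposite of that in the normalized intensities of the same table. Its log2 size correlated at -1 across probes with the ratio formed from those columns, and at -0.99 (Pearson) and -0.98 (Spearman) with the log2 fold changes given here. Genes are not independent replicates in these correlations. The sign was opposite for 93.2% of the probes, and 89 of 90 probes of the triplicated list had a negative deposited fold, with a median of -1.45. In the authors' deposited table, Dnah11 stands at -343 and S100a8 at -10.1. Directions in the present text follow the sample labels and the scanner files. The authors' deposited table gives 2293 probes with p under 0.05, where 1503.3 would be so by chance, and 0 with a corrected p under 0.05, the lowest being 0.081. Its p-values differed from those of a paired comparison by replicate number by a median of 5.0e-07.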

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

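The alternative with the authors' normalized intensities and the random-block fits with an array left out were chosen after the data were seen; the other alternatives were planned. The median of the triplicated list stayed above 0 and past camera under all 19 alternatives run, between 0.49 and 0.54. The fit without a block called 2 genes, 1 of them on neither segment's list. These numbers were 1 and 0 with the quantile scaling, normexp, no filter on dim probes, probes well above background on all 6 arrays, every probe tested by itself, moderation with a trend and the authors' normalized intensities, each without a block, and also with the replicate block as a fixed term. With the replicate block as a random effect the numbers were 122 in all, 86 on neither list, 33 on the triplicated list and 3 on the deleted list. A block takes out the spread between slides; a fixed block also leaves fewer residual degrees of freedom.

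The median of the deleted list was -0.60 with normexp, -0.61 with no filter on dim probes and -0.61 with the mean of a gene's probes, and the list no longer passed; the cause was not tested. With an estimated correlation the list, at -0.83, did not pass, and fry called it higher at the same median of -0.83. The number of lists past the set test was 15 with camera, 1 with an estimated correlation and 2 by fry. The latter settings let the correlation within a list count. With the estimate, this is not the only difference from camera at the preset correlation. For the triplicated list the estimate was -0.0086, below the preset 0.01. Its unadjusted camera p still went from 5.3e-99 at the preset to 1.2e-05 with the estimate. Among the lists that lost the call, the estimate was below the preset 0.01 for the deleted (-0.18), monocyte (-0.069), astrocyte (-0.035) and pericyte (0.0046) lists. A higher correlation therefore does not account for their lost calls with an estimated correlation. For the other lists that lost the call the estimate was above 0.01, up to 0.62 for the interferon list. How far the correlation accounts for their lost calls was not tested.

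Without each array in turn, the count of genes was 1 to 1 and on neither list 0 to 0, the median of the deleted list -0.90 to -0.71, the number of lists 7 to 17, and the random-block count 4 to 163. The number of lists was 9 without Ts1Cje replicate 1 and 7 without wild-type replicate 2. The midbrain and hindbrain list ran from -0.51 without wild-type replicate 3 to 0.18 without wild-type replicate 1. Without Ts1Cje replicates 3 and 2, the mitosis list was at -0.16 and 0.0268 and the DNA replication list at -0.0982 and 0.0679; the cause of these reversals was not tested. Signal over background limits what could be tested: transcripts dim in both groups, such as Xist, were left out. Over the single genes and lists named in the text, 3714 values under an alternative kept their sign and side of the threshold, 83 kept the sign but no longer passed, and 44 newly passed. The sign changed for 163 others: the 3 reversals above, and 160 values that passed under neither setting.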

Other observations

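The tests of granulocyte genes, Dnah11 and the slides below, and the genes named in this part outside the fixed rule, were chosen after the results were seen; the comparison with other splits of the arrays was planned. The stefin A genes that were higher stand side by side on chromosome 16. Besides Csta2, Stfa2 and Stfa3, the neighbours Stfa1, Cstdc4 and Cstdc5 rose in the random-block fit, with log2 fold changes of 3.33 ± 0.57, 3.24 ± 0.52 and 3.52 ± 0.63 (random-block adjusted p = 0.022, 0.031 and 0.026), while Gm6815 within the cluster was at -0.02. Slc15a2, a peptide transporter gene near the cluster, fell, at -1.08 ± 0.46 (random-block adjusted p = 0.046). Ifi27l2a, a neighbour of Ifi27 on chromosome 12, was at 1.52 ± 0.24 (random-block adjusted p = 0.0041), and at least 1.48 on each slide.

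Genes for interferon and interleukin receptor subunits lie on the triplicated segment. Ifnar1 was at 0.55 ± 0.13, Ifnar2 at 0.64 ± 0.10 and Ifngr2 at 0.58 ± 0.12, and these 3 rose in the random-block fit (adjusted p = 0.024, 0.016 and 0.045), while Il10rb at 0.60 ± 0.29 did not pass (0.099). Lyz2, a lysozyme gene of myeloid cells, at 0.90 ± 0.18, and Folr2 and Cbr2, genes of tissue macrophages, at 0.61 ± 0.18 and 0.67 ± 0.16, rose in the same fit (adjusted p = 0.011, 0.048 and 0.032). The Cbr2 probe was well above background on 1 of 3 wild-type arrays, and the Cstdc4 probe on 2 of 3.

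The granulocyte list was higher in Ts1Cje by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.13) or by fry (0.12), and 5 of its 14 members passed with the slide as a random block, 0 without a block. More blood of every kind would raise erythroid genes as much. The highest within-slide median of the erythroid list was 0.10, against a lowest of 0.68 for the granulocyte list. By the mean of its members, the erythroid list was lower in Ts1Cje on slides 1 (2.88 against 3.31) and 2 (2.94 against 3.05). It was higher on slide 3 (3.40 against 2.84), where the granulocyte mean was -1.63 against -3.20. These values argue against blood of every kind on slides 1 and 2, and less clearly on slide 3. A like rise of macrophages is argued against by the highest within-slide median of their list, 0.24. Differences between slides cancel within slides, since each holds 1 array of each group, so that comparison says nothing about them. Of the 14 tested members, 10 were well above background on all wild-type arrays, and 0 stand on another list. More granulocytes or their precursors in the tissue taken, from the genotype or from dissection, may account for the pattern and stay open as a hypothesis. Some lists of other non-neural tissue also had medians above 0. These were meninges at 0.19 (16 of 16 members above 0), pericytes at 0.15 (11 of 12) and mast cells and megakaryocytes at 0.14 (7 of 9). Skin, muscle and cartilage stood at 0.12 (11 of 16). None of these lists passed with an estimated correlation. Choroid plexus, at 0.01 (8 of 15), and eye, lens and retina, at 0.05 (8 of 14), lay nearer to 0. Hypothalamus and pituitary lay below 0, at -0.13 (2 of 12 members above 0). A difference in dissection stays open. Elane and Prtn3, genes of the same granules as Mpo, did not pass over all genes in any of the 3 fits.

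Dnah11 was higher although its segment has lost 1 copy. Activation of the whole segment is argued against by the highest log2 fold change of the other tested members, -0.61. Whether the signal of its probe comes from another transcript cannot be told apart from a change of Dnah11 itself, because the number of other Dnah11 probes on the array is 0. A rearranged chromosome end that drives the gene may be 1 explanation; it was not tested here.

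Few genes passed without the slide in the fit. The consensus correlation of arrays on 1 slide was 0.822, so arrays of a slide share differences, from the slide or from the litter, which stay open since each slide holds 1 replicate number. The count depends on the kind of block: it was 2 without a block, 122 with the slide as a random block and 1 with the slide as a fixed block. In the simulation the fixed block recovered more changed genes than no block, 73.1% against 32.8% at 2-fold, so why the fixed block called 1 gene here stays open. The 122 became 4 to 43 without any 1 of 5 arrays, and 163 without wild-type replicate 3.

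The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split of 10 with as many genes past the threshold, 2 against at most 0, with as many in the random-block fit, 122 against at most 0, and with as many on neither segment's list, 1 against at most 0. It was also the 1 split with as large an absolute median of the triplicated list (0.52 against at most 0.20), of the deleted list (0.83 against 0.35) and of the granulocyte list (1.24 against 0.64). All splits used the genes kept by the filter on the real groups. Of the 14 tested granulocyte members, 10 were well above background on all wild-type arrays. The others were kept through the Ts1Cje arrays alone, which favours the real split. For the number of lists past camera, 3 of the 10 splits gave as many: 15 in the real split and up to 17 in others. Among the other splits that part all 3 pairs the numbers were 17, 16 and 10. Each other split holds both genotypes on both sides, unevenly, so it keeps part of the genotype difference. These counts therefore cannot tell whether the number of lists past camera at the preset correlation is particular to the genotype. The splits that part 1 pair gave 1 to 9. Single lists passed camera under other splits too: of the 15 lists, 13 did so in at least 1 of the 9 others, among them the triplicated list in 6, the interferon, GABAergic and mitosis lists in 4 each, and the granulocyte list in 2. All 3 others that part the pairs called the triplicated, GABAergic and mitosis lists.

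The filter on the real groups can favour the real split for single lists too. For 5 of the 15 lists (triplicated, deleted, granulocyte, meninges and astrocyte) no other split gave as large an absolute median, narrowly so for meninges (0.19 against at most 0.17) and astrocytes (0.12 against at most 0.09). For the other 10 at least 1 did: 1 for interferon (0.50 against up to 0.69) and hypoxia (0.17 against 0.20), 2 for pericytes (0.15 against 0.18), 3 for the GABAergic (0.10 against 0.17), mast cell (0.14 against 0.22) and skin lists (0.12 against 0.17), 4 for the endothelial list (0.08 against 0.20), and 7 for the monocyte (0.06 against 0.27), midbrain (0.27 against 0.79) and mitosis lists (0.08 against 0.13).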
